A study of Mus musculus with 10 samples.

How the data were processed

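The samples were 10 exo-Hi-C libraries of mouse embryonic stem cells, the line ES-E14TG2a, in 5 genotypes with 2 libraries each: WT, E1-KO, E2-KO, E3-KO and E1&E3-dKO. Exo-Hi-C is Hi-C with an exonuclease step after proximity ligation that removes linear DNA. The labels name 2 exonuclease combinations, LRC and LIC, without saying which library received which. They also do not say that replicates came from separate cultures or clones, so the p-values measure only the spread between these samples. The titles of 4 libraries begin with w326 (WT replicate 1, both E2-KO libraries and E3-KO replicate 2) and those of the other 6 do not.

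Per the labels, reads were processed on mm9 with HiC-Pro 2.10.0 and HOMER, whose version is not given. Each library has 2 deposited files, 20 in all, and replicates were not pooled. The deposited interaction list gives pairs of 10 kb bins with a count of reads that is not scaled, a p-value and an adjusted p-value of at most 0.01, and for each bin a bias factor, which is a ratio to an average bin. The tool behind it is not stated. The deposited TAD list gives the ends of each TAD with a score from the authors, never under 1.5. Neither file gives the number of reads per library, so total depth is unknown. The list of WT replicate 2 holds every pair in both orientations, 932 lines for 466 pairs, and each pair was used once.

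A relative depth was recovered from the interaction lists. For each listed pair the Poisson mean that returns the deposited p-value at the deposited count was solved for and divided by the bias factors of both bins, which gives the contacts expected for an average pair at that distance. Tested on simulated data, the recovery had a largest relative error of 1.13e-07. The simulated p-values came from the same Poisson formula, so this checks only the solving. Whether the lists were made with that formula, and whether the result follows the reads of a library, was not tested by it. Expected contacts per pair of bins at 1 Mb served as the measure of depth. Expected contacts at 0.1, 2, 5, 10, 20, 40, 60 and 80 Mb were divided by this level to give the decay with distance. If contacts behind the doubled list of WT replicate 2 were also doubled, its recovered depth is too high, while its ratio between distances is unaffected.

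Interactions were taken as shared when both ends lay within 1 bin, TAD boundaries when they lay within 25 kb, which is 20 kb in whole bins, and TADs when they overlapped reciprocally by at least 80%. A feature was lost in a genotype when both WT libraries and neither knockout library held it, and gained in the reverse case. Beside each lost and gained count stand the same counts for the other ways to split those 4 libraries into pairs. Boundaries expected by chance came from 20 rotations along each chromosome. Overlaps between knockouts that share the WT libraries were set beside the product expected for independent lists and beside 100 simulated sets of libraries without effects. These sets keep the number of features of each library and the recurrence of each feature only on average. Each feature was drawn separately in each library, so a feature of 1 library can fall in more than 1 simulated library, which adds simulated gains. Where it falls in both simulated WT libraries it adds simulated losses. Lost and gained counts were set beside the same sets.

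Genotype differences were tested with an exact permutation over all pairings of the libraries, with the spread within pairs as the statistic (one-sided); the smallest p it can give is 0.00106. Similarity of libraries of a genotype used the same pairings, with the mean overlap as the statistic (one-sided). WT was compared with all knockouts over the 45 choices of 2 libraries (two-sided), where the smallest p is 0.0222. For 2 libraries against 2 the smallest exact p is 0.333, so each knockout is compared with WT by its values and by the other splits; a test of a lone knockout with the spread pooled over all genotypes was not run. The 13 tests planned were adjusted by Benjamini-Hochberg. These comparisons, the rule for named regions and their alternatives were fixed before the data were examined; the decay with distance, the relation of TADs to depth and the comparison of the double with the single knockouts (28 choices with E2-KO, 15 without) were added later.

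Named regions were chosen by rule: for each knockout genotype the 5 lost and 5 gained interactions with the smallest mean p and the 5 lost and 5 gained boundaries with the highest mean score, plus the 5 interactions and 5 TADs found in most libraries. Positions are in mm9. The gene table at hand is for GRCm38, and on 9 chromosomes deposited positions lay beyond its last gene, up to 152.53 Mb against 145.324 Mb on chromosome 7. Interactions and TADs at gene loci, with 6 gene lists, were therefore not run, and no gene is assigned to a region.

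Alternatives were a stricter adjusted p, autosomes only, the same number of best calls per library, other tolerances, another overlap index, another summary of distance and length, TADs in the upper 75% of scores, blocks by replicate number and by title, and leaving out each library. Later additions were a doubled adjusted p in WT replicate 2, interactions under 2 Mb only, and other reference distances of the decay. Tested on simulated data for E1-KO against WT, 99 of 100 planted lost boundaries and 96 gained boundaries were recovered among 2567, and 8 of 200 null draws passed 0.05 in the test over pairings. The simulated boundaries were those of at least 8 real libraries. Apart from the planted changes, each was placed in every library, moved by at most 1 bin, without missed or false calls. The recovery therefore tests the matching rule and not its accuracy on calls as variable as the deposited ones. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.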

Results

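Chromosome contacts were measured by exo-Hi-C in WT mouse embryonic stem cells and in cells lacking the enhancers E1, E2, E3, or both E1 and E3 (E1&E3-dKO), with 2 libraries per genotype. The labels do not give the position of the enhancers. The lists held between 466 interactions in WT replicate 2 and 6014 in E1&E3-dKO replicate 2, all within chromosomes, and between 2715 TADs in E1-KO replicate 1 and 7962 in E2-KO replicate 1. Recovered depth, in contacts expected per pair of 10 kb bins at 1 Mb, was 0.191 and 0.207 in WT, 0.246 and 0.114 in E1-KO, 0.0147 and 0.0835 in E2-KO, 0.171 and 0.0721 in E3-KO, and 0.110 and 0.0689 in E1&E3-dKO. The median interaction rested on 3 to 15 reads.

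In E1-KO the median distance of interactions averaged 2.06 Mb ± 2.62 (SD, n = 2), with 0.21 and 3.91 Mb in its libraries, against 29.8 Mb ± 16.3 in WT (n = 2). E2-KO libraries had medians of 30.71 and 1.99 Mb, and with the same number of best interactions per library the log10 difference of E2-KO from WT was -1.27. E1-KO libraries held 161.5 ± 40.3 interactions of 20 Mb and more, against 460.5 ± 224 in WT, and their values lay below both WT libraries. E2-KO libraries held 939 and 527 interactions under 2 Mb, against 357 and 43 in the WT libraries. E1&E3-dKO averaged 3432.5 ± 3651 interactions, with 851 in replicate 1 and 6014 in replicate 2. Over all pairings of the libraries the spread within genotypes was not smaller than chance for the number of interactions (exact permutation p = 0.592), for their distance (p = 0.186) or for their reads (p = 0.206), and adjusted p was at least 0.514 for the 13 tests; at an adjusted p of 0.001 for the interactions, distance passed unadjusted (exact permutation p = 0.0381). Knockouts exceeded WT by 0.83 on the log2 scale in number (exact permutation p = 0.422), by 0.11 without WT replicate 2 and by 1.56 without WT replicate 1; without E1&E3-dKO replicate 2 the difference of that genotype from WT was 0.14.

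**Figure D1:**
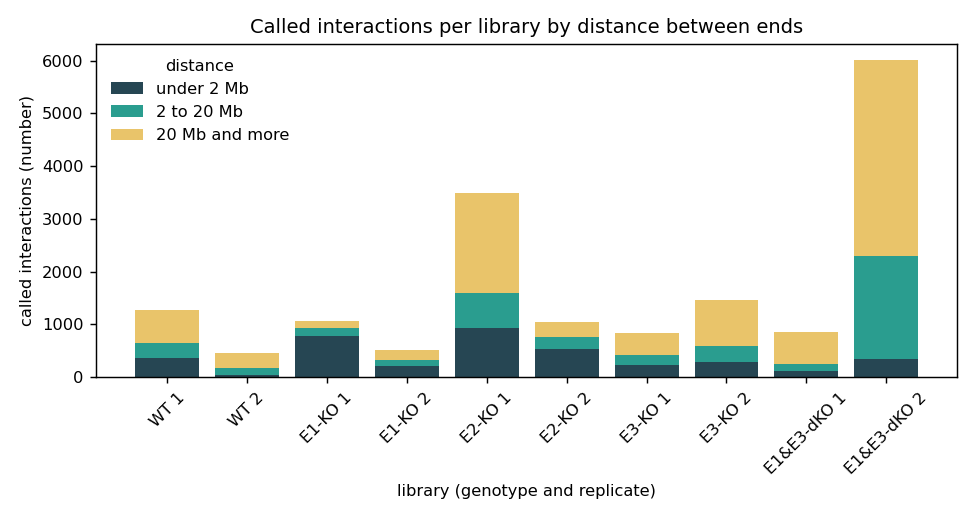
Called interactions per library (vertical axis, number), stacked by the distance between their ends, for 2 libraries of each of 5 genotypes. Totals run from 466 in WT replicate 2 to 6014 in E1&E3-dKO replicate 2, of which 3713 span 20 Mb and more.

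Most interactions were listed in a lone library. Of 13962 distinct interactions, 13192 occurred in 1 library, 207 in at least 5 and 26 in all 10. Those of at least 5 libraries spanned a median of 0.83 Mb, against 34.11 Mb for those of 1 library, and 37 of them lay on chromosome 12, 31 on chromosome 7 and 20 on chromosome 4. Between the 1 Mb windows starting at 39 and 46 Mb of chromosome 7 there were 13, the most of 104 pairs of windows that held any. The interactions of all 10 libraries with the smallest mean p joined 3.035 and 6.025 Mb of chromosome 14 (mean p-value in the lists 2.2e-38), 21.555 and 25.185 Mb and 18.325 and 25.095 Mb of chromosome 12, 39.205 and 46.585 Mb of chromosome 7, and 66.085 and 66.735 Mb of chromosome 13. Among TADs of all 10 libraries, those with the highest mean score lay on chromosome 12 from 19970000 to 20340000 (4.66 ± 4.23, SD, n = 10), chromosome 10 from 117640000 to 117740000 (4.33 ± 4.26), chromosome 13 from 65610000 to 65770000 (4.203 ± 2.11) and from 21930000 to 22140000 (3.97 ± 0.3299), and chromosome 5 from 14910000 to 15220000 (3.77 ± 1.48).

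By the Jaccard index of the full lists, libraries of a genotype did not share detectably more features than libraries of different genotypes. Lists of unequal size limit this index, as with the 851 and 6014 interactions of the E1&E3-dKO libraries. The mean Jaccard index of interactions was 6.99% ± 4.44 (SD, 5 pairs) within genotypes and 6.06% ± 3.77 (40 pairs) between them (exact permutation p = 0.163). For TAD boundaries the values were 31.9% ± 8.99 and 31.0% ± 8.66 (exact permutation p = 0.309), and for TADs 24.5% ± 12.3 and 23.4% ± 10.7 (exact permutation p = 0.265). When each library gave the same number of best interactions, the index was higher within genotypes by 0.0407 (exact permutation p = 0.0275), with the overlap coefficient it was higher by 0.0617 (exact permutation p = 0.0286), and without E2-KO replicate 1 the difference in interactions was -0.00880. Without E2-KO replicate 2 the difference in TADs was 0.0589 (exact permutation p = 0.0328), and without WT replicate 2 it was -0.0154. Pairs of libraries titled w326 shared 8.12% of interactions against 5.86% in other pairs (exact permutation p = 0.186 over choices of 4 libraries), 25.01% of boundaries against 32.0% (exact permutation p = 0.867) and 15.7% of TADs against 24.7% (exact permutation p = 0.881).

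Cells lacking E1 lost 10 interactions and gained 33. The losses with the smallest mean p joined 4.865 and 8.115 Mb (mean p-value in the lists 3.61e-20) and 4.395 and 7.765 Mb of chromosome 14, 19.855 and 72.065 Mb and 19.865 and 72.085 Mb of chromosome 8, and 39.215 and 46.515 Mb of chromosome 7. Both chromosome 8 pairs lie side by side with the same mean p (7.54e-17), so they appear to count the same WT calls 2 times. The gains joined 130.715 and 130.965 Mb of chromosome 6 (1.22e-20), 66.585 and 66.835 Mb of chromosome 17, 68.445 and 68.525 Mb of chromosome 13, 53.335 and 54.045 Mb of chromosome 14, and 96.145 and 96.195 Mb of chromosome 3. In this order 3, 1, 6, 4 and 5 of the 6 libraries of the other knockouts also held them. Close to the chromosome 6 pair lay 130.695 and 130.945 Mb, held by all 10 libraries, so this gain borders on an interaction present in WT. Of the 3612 boundaries in both WT libraries E1-KO lost 448, with the highest mean scores on chromosome X at 165.75 Mb (2.73) and 119.23 Mb, chromosome 4 at 113.96 Mb, chromosome 12 at 56.35 Mb and chromosome 5 at 5.51 Mb. It gained 373, led by chromosome 13 at 68.43 Mb (3.34), chromosome 14 at 21.14 and 7.3 Mb, chromosome 17 at 36.96 Mb and chromosome X at 166.19 Mb. It lost 259 TADs and gained 205. Lost and gained interactions came to 43, against 99 and 32 for the other splits of these 4 libraries, and boundaries to 821 against 857 and 650, so neither exceeded every other split, while TADs came to 464 against 411 and 333. Simulated libraries without effects gave on average 36.8 lost and 26.2 gained interactions, 459 lost and 459.8 gained boundaries and 262 lost and 251 gained TADs. Against WT replicate 2 alone, which like E1-KO has no w326 title, 373 interactions were lost and 79 gained. Without WT replicate 2 the loss was 984, and the gain was 316 without E1-KO replicate 1 and 711 without replicate 2.

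Cells lacking E2 gained 275 interactions and lost 6, and gained 113 when each library gave the same number of best interactions. The gains spanned a median of 0.39 Mb, 212 of them under 2 Mb, with 37 on chromosome 13 and 31 on chromosome 12. The gains with the smallest mean p joined 18.335 and 25.075 Mb of chromosome 12 (1.46e-63), 145.455 and 146.685 Mb of chromosome 4 (9.99e-61), 22.365 and 22.805 Mb (7.2e-55) and 73.735 and 74.315 Mb of chromosome 8, and 66.035 and 66.925 Mb of chromosome 13 (9.98e-49); the chromosome 8 pair near 22 Mb and the chromosome 13 pair were in 0 of the 6 libraries of other genotypes. The chromosome 12 pair, the chromosome 4 pair and the chromosome 8 pair at 73.735 and 74.315 Mb were in 4, 1 and 3 of those 6 libraries. Close to the chromosome 12 pair lay 18.325 and 25.095 Mb, held by all 10 libraries. The chromosome 8 pair at 73.735 and 74.315 Mb lay close to 73.715 and 74.325 Mb, also held by all 10, so these gains border on interactions present in WT. The losses were led by 4.865 and 8.115 Mb of chromosome 14 and both pairs of chromosome 8 lost in E1-KO, which appear to rest on the same WT calls. Next came 145.045 and 146.015 Mb and 145.195 and 146.615 Mb of chromosome 4. Close to the latter lay 145.215 and 146.635 Mb, held by 9 of the 10 libraries and so not missing from both of E2-KO. E2-KO lost 502 boundaries, among them chromosome 12 at 21.01 and 21.68 Mb (mean score 5.62), chromosome 13 at 68.09 Mb, chromosome 4 at 145.29 Mb and chromosome 12 at 83.16 Mb. It gained 1361, though with the same number of best TADs from each library 821 were lost and 396 gained. Among the gained were chromosome 13 at 68.43 and 68.54 Mb (15.6), and chromosome 7 at 24.42 and 24.55 Mb (9.24) and 66.9 Mb (8.38). In TADs 441 were lost and 240 gained. The gain depended on the rule, with 510 TADs at a reciprocal overlap of 50% and 97 with the same number of best TADs.

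In E2-KO the lost and gained features exceeded the other splits of its 4 libraries with WT: 281 interactions against 13 and 24, 1863 boundaries against 1005 and 1193, and 681 TADs against 417 and 442. Simulated libraries with no genotype effect keep the number of features of each library only on average. They gave a mean of 115 lost and 1983 gained boundaries and 105 lost and 906 gained TADs, against which E2-KO lost more and gained fewer. For interactions the simulated libraries gave 20.6 lost and 171 gained, against which E2-KO gained more and, like every knockout, lost fewer. The way these libraries are drawn adds losses, so the lower number of losses says nothing about the knockouts. E2-KO replicate 1 had the lowest recovered depth of all libraries, 0.0147. The exact p cannot pass 0.333 for 2 libraries against 2. Of the 45 choices of 2 libraries, the E2-KO pair held the most interactions found in no other library, 118 against 51 at the next highest, while its 503 boundaries and 105 TADs of this kind were exceeded by other choices. Both E2-KO libraries are titled w326, and against WT replicate 1 alone, also w326, 293 interactions were gained and 1036 lost. Without E2-KO replicate 2 the gain was 3040 interactions and the loss 21, without replicate 1 the gain was 675, and without WT replicate 1 the loss was 363.

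Cells lacking E3 gained 24 interactions and lost 3. The losses joined 19.855 and 72.065 Mb of chromosome 8 (7.54e-17), 39.355 and 46.625 Mb of chromosome 7, and 57.435 and 82.635 Mb of chromosome 6. The adjacent chromosome 8 pair at 19.865 and 72.085 Mb, with the same mean p in WT, was not lost in E3-KO. An E3-KO library therefore held a call there, and the chromosome 8 loss depends on the matching of bins. The gains with the smallest mean p joined 22.235 and 23.345 Mb of chromosome 13 (1.92e-17), 7.155 and 8.135 Mb and 24.025 and 24.045 Mb of chromosome 17, 14.945 and 15.115 Mb of chromosome 5, and 24.275 and 24.655 Mb of chromosome 7. In this order 5, 2, 2, 4 and 5 of the 6 libraries of the other knockouts also held them. E3-KO lost 341 boundaries, led by chromosome 13 at 68.09 Mb (2.94), chromosome X at 119.23 Mb and chromosome 5 at 5.51, 10.64 and 10.87 Mb. It gained 520, led by chromosome 13 at 68.43 and 68.54 Mb (5.40). Next came chromosome 17 at 14.23 Mb, chromosome 14 at 20.9 Mb and chromosome 9 at 4.46 Mb. In TADs 212 were lost and 232 gained. With the same number of best TADs from each library 268 boundaries and 130 TADs were gained. Under that rule more of each were lost than gained, so the excess of gains depended on the rule. The sums of 27 interactions, 861 boundaries and 444 TADs lay below both other splits of these libraries, at 35 and 44, 954 and 890, and 459 and 455. Simulated libraries without effects gave on average 28.8 lost and 67.8 gained interactions, 300.5 lost and 805 gained boundaries and 190.1 lost and 418 gained TADs. Gained interactions numbered 1239 without E3-KO replicate 1, 628 without replicate 2 and 64 without WT replicate 1. Lost ones numbered 14, 11 and 367 in the same order, and 1036 without WT replicate 2.

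Cells lacking both E1 and E3 lost 10 interactions and gained 16. The losses joined 4.185 and 8.095 Mb (1.34e-15) and 4.195 and 6.185 Mb of chromosome 14, 39.325 and 46.445 Mb and 39.355 and 46.625 Mb of chromosome 7, and 145.725 and 146.555 Mb of chromosome 4. Close to the chromosome 7 pair at 39.325 and 46.445 Mb lay 39.305 and 46.425 Mb, held by all 10 libraries, the double knockout included. The gains joined 68.445 and 68.525 Mb (1.64e-13) and 65.705 and 66.825 Mb of chromosome 13, 68.395 and 68.625 Mb of chromosome 2, 179.875 and 180.085 Mb of chromosome 1, and 30.455 and 32.045 Mb of chromosome X. In this order 6, 2, 3, 3 and 4 of the 6 libraries of the other knockouts also held them. It lost 431 boundaries, led by chromosome 13 at 68.09 and 68.59 Mb (2.94), chromosome 2 at 103.84 Mb, chromosome 12 at 114.95 Mb and chromosome 19 at 8.8 Mb. It gained 650, led by chromosome 13 at 68.43 and 68.54 Mb (4.41) and chromosome X at 34.8 Mb (3.34, in 0 of the 6 libraries of other genotypes). Next came chromosome 7 at 17.67 Mb and chromosome 14 at 52.49 Mb. With the same number of best TADs from each library 355 boundaries were gained. Under that rule more boundaries were lost than gained, so the excess of gains depended on the rule. In TADs 302 were lost and 209 gained. Boundaries came to 1081 against 996 and 940 for the other splits and TADs to 511 against 445 and 446, while interactions came to 26 against 20 and 50. Simulated libraries without effects gave on average 14.6 lost and 288 gained interactions, 283 lost and 879 gained boundaries and 189 lost and 423 gained TADs. Gained interactions numbered 5833 without E1&E3-dKO replicate 1, 738 without replicate 2 and 37 without WT replicate 1, which leaves only libraries not titled w326. Lost ones numbered 18, 24 and 370 in the same order, and 1071 without WT replicate 2.

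A region of chromosome 13 separated every knockout library from both WT libraries. The interaction between 68440001 to 68450000 and 68520001 to 68530000, 80 kb apart, was listed in all 8 knockout libraries with 14 to 30 reads and in neither WT list. A TAD from 68.43 to 68.54 Mb was present in 7 knockout libraries with scores from 3.28 to 21.3, and E1-KO replicate 1 held a TAD from 68.09 to 68.45 Mb (2.83). In both WT libraries a TAD of 520 kb from 68.09 to 68.61 Mb covered the region, with scores of 2.86 and 3.02. It was the only interaction of this kind, beside 7 boundaries, at 68.43 and 23.78 Mb of chromosome 13, 41.84 and 82.85 Mb of chromosome 6, 108 Mb of chromosome 4, 20.31 Mb of chromosome 16 and 89.53 Mb of chromosome 12, and 2 TADs, both on chromosome 16, from 32.49 to 32.7 Mb and from 20.31 to 20.49 Mb. Those outside the rule for named regions were chosen after their values were seen. Of the 45 choices of 2 libraries, 20 gave at least 1 interaction held by every other library and neither chosen one, 43 gave at least 7 boundaries and 31 at least 2 TADs, so the choice of the WT libraries was not unusual in any of them.

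**Figure D2:**
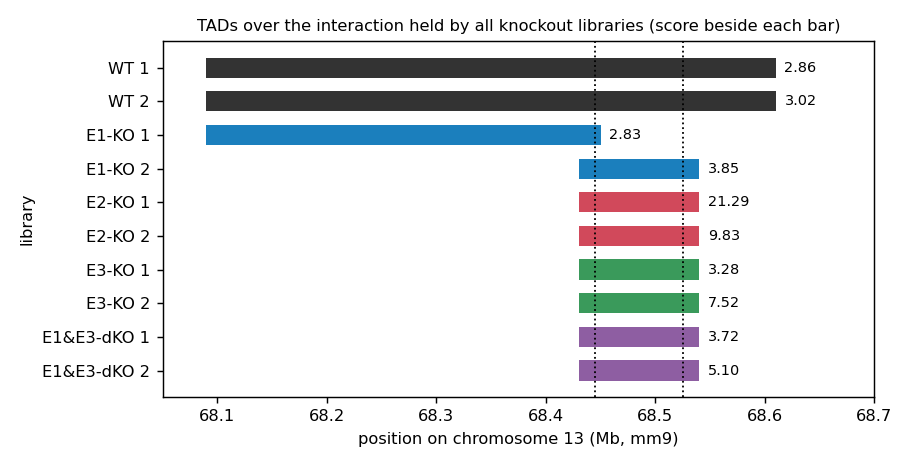
TADs overlapping the interaction held by all knockout libraries, by position on chromosome 13 (Mb, mm9), 1 bar per TAD with its score beside it and dotted lines at the ends of the interaction. Both WT libraries hold a TAD from 68.09 to 68.61 Mb, and 7 of the 8 knockout libraries one from 68.43 to 68.54 Mb.

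TADs were on average most numerous and shortest in the lists of E2-KO. It held 6088.5 ± 2650 TADs (SD, n = 2), 1.89-fold the 3213 ± 474 of WT (n = 2), and its libraries of 7962 and 4215 both exceeded the WT libraries of 2878 and 3548. E1-KO held 3181.5 ± 660, E3-KO 4079.5 ± 1102 and E1&E3-dKO 4108.5 ± 1078. E3-KO replicate 2 with 4859 TADs and E1&E3-dKO replicate 2 with 4871 exceeded E2-KO replicate 2. Their median TADs, of 130 and 120 kb, were also shorter than in that library. The median TAD was 250 and 210 kb long in WT and 90 and 150 kb in E2-KO, while TADs covered 1086 Mb ± 82.1 in WT and 1072 Mb ± 36.5 in E2-KO. The spread within genotypes was not smaller than chance for the number (exact permutation p = 0.326) or the length of TADs (exact permutation p = 0.353), and knockouts exceeded WT by 0.37 on the log2 scale (exact permutation p = 0.356). Without E2-KO replicate 2 the log2 difference of E2-KO from WT was 1.32, and without replicate 1 it was 0.40. WT boundaries were found in knockout libraries at 51.2% in E2-KO replicate 1 to 66.6% in E3-KO replicate 1, against 9.29% to 28.4% for rotated boundaries and 63.8% between the WT libraries.

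The number of TADs fell with recovered depth. Reads at interactions held by at least 5 libraries did not rise with this measure (log-log slope -0.0870), so it may not stand for the reads of a library. Over the 9 libraries that list each pair once, Pearson's r of the log2 number with log2 depth was -0.981 (exact permutation p = 8.27e-06, adjusted 3.31e-05 over 8 relations) and Spearman's rho -0.983 (exact permutation p = 4.96e-05), with r of -0.949 without the 2 libraries farthest from the median depth. Outside E2-KO, 7 libraries gave r of -0.959 and rho of -0.964 (exact permutation p = 0.00278). Among the 6 libraries not titled w326 r was -0.851 (exact permutation p = 0.0306), while rho was -0.714 and did not pass (exact permutation p = 0.136). Without the 2 extreme ones r was -0.0593, so there it rests on those. This set includes WT replicate 2, which the fits above leave out and whose recovered depth may be doubled. The 4 titled w326 are too few for a correlation and gave a slope of -0.389 against -0.343. TAD length rose with depth over the same 9 libraries (r = 0.938, exact permutation p = 5.51e-06). This relation was examined after the data were seen.

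**Figure D3:**
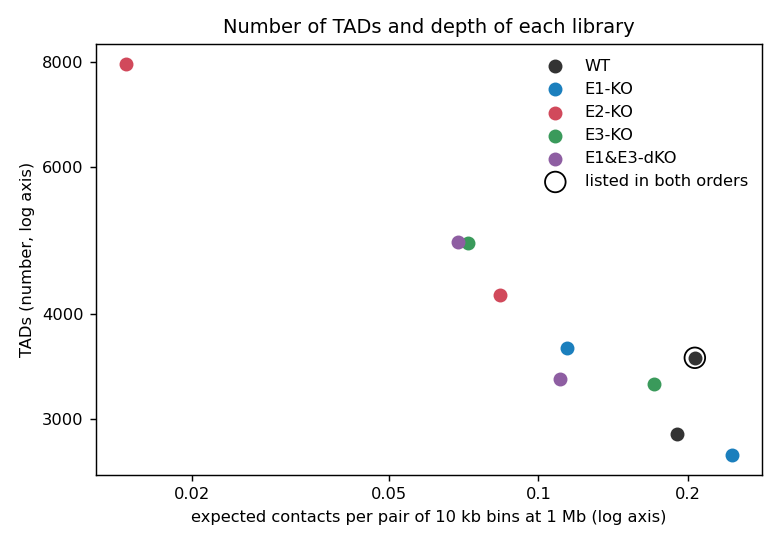
Number of TADs (vertical log axis) against expected contacts per pair of 10 kb bins at 1 Mb (horizontal log axis), 1 point per library coloured by genotype, with a ring around the library listed in both orientations. E2-KO replicate 1 has the lowest depth, 0.0147, and the most TADs, 7962.

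E1&E3-dKO was compared with E1-KO and E3-KO to see whether the same features changed. The double knockout and E1-KO lost 156 boundaries in common, and the double knockout and E3-KO 123, against 53.5 and 40.7 for independent lists and 161 and 128 in simulated libraries without effects that share the WT controls. All 3 genotypes lost 59 boundaries in common (simulated 86.8) and gained 15 (simulated 50.2). Gained boundaries in common numbered 71 with E1-KO and 77 with E3-KO, against 12.3 and 17.1 for independent lists and 116 and 174 in the simulated libraries, whose lists of gains were longer than the observed ones (459.8 in E1-KO, 805 in E3-KO and 879 in E1&E3-dKO on average). Among the 15 ways to pair the 6 knockout libraries, the real pairing gave the largest sum of overlaps of lost boundaries (407, lowest 380), and 2 of 15 gave a sum as large for lost TADs, 2 for gained boundaries, 3 for gained TADs, 11 for lost interactions and 4 for gained interactions, the real pairing included. Of the features of the double knockout, 211 lost and 517 gained boundaries were in neither of the other genotypes. Shared lost TADs numbered 107 and 88 (simulated 113 and 96.6) and shared lost interactions 2 and 1 (simulated 13.3 and 12.5). Shared gained interactions numbered 4 and 2 (simulated 3.86 and 8.82). All 3 genotypes gained 1 (simulated 1.3), the chromosome 13 interaction at 68.445 and 68.525 Mb. A split of the controls would leave 1 WT library per comparison and was not run. Losses shared with the double knockout did not exceed those of simulated libraries with the same controls. The way those libraries are drawn adds losses, so that comparison cannot decide whether there was overlap beyond the shared controls. Without WT replicate 1 the boundaries lost in all 3 numbered 777, and without WT replicate 2 300.

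Expected contacts over very long distances, as recovered from the lists, were highest relative to those at 1 Mb in E1&E3-dKO and lowest in E2-KO. At 40 Mb they stood at 3.00% ± 0.0323 of the 1 Mb level in WT (SD, n = 2), 3.37% ± 0.0132 in E1-KO, 2.68% ± 0.0436 in E2-KO, 3.16% ± 0.150 in E3-KO and 3.88% ± 0.327 in E1&E3-dKO, each group apart from both WT libraries. At 80 Mb E1&E3-dKO stood at 1.89% ± 0.331, 1.91-fold the 0.990% ± 0.0962 of WT. The spread within genotypes at 40 Mb, 0.06 on the log2 scale against 0.19 over all libraries, was the smallest of all pairings (exact permutation p = 0.00106, the smallest possible, adjusted 0.00847 over 8 distances). Exact permutation p was 0.00423 at 60 Mb and 0.00952 at 80 Mb, and between 0.0815 and 0.176 from 100 kb to 20 Mb. No difference of the knockouts as a whole from WT was detectable at 40 Mb (exact permutation p = 0.489). Over pairings that keep the make-up of titles p was 0.00185 (exact permutation). Without E1&E3-dKO replicate 1 its log2 difference from WT at 40 Mb was 0.45, and without replicate 2 0.28. For E3-KO this difference ranged from 0.0247 to 0.122 over left-out libraries. E3-KO replicate 1 stood at 3.05%, close to the 3.03% of WT replicate 1. A floor of random ligation, which adds the same amount at every distance, could not be excluded for either E1&E3-dKO library. The distances were chosen after the data were seen.

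**Figure D4:**
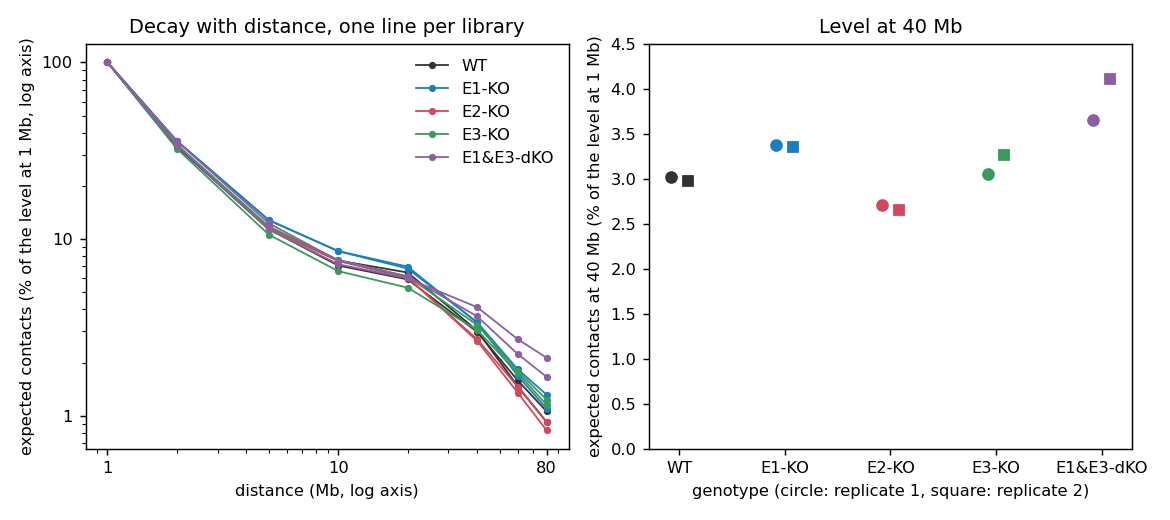
Left, expected contacts in percent of the level at 1 Mb (log axis) against distance in Mb (log axis), 1 line per library coloured by genotype. Right, the level at 40 Mb for each library (circles replicate 1, squares replicate 2), from 2.65% in E2-KO replicate 2 to 4.11% in E1&E3-dKO replicate 2.

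Against all 6 libraries of E1-KO, E2-KO and E3-KO, E1&E3-dKO stood higher by 0.34 on the log2 scale at 40 Mb (exact permutation p = 0.0714 over 28 choices), by 0.59 at 60 Mb and by 0.80 at 80 Mb (exact permutation p = 0.0357 for both, the smallest possible). After adjustment over 8 measures p was 0.190 at 40 Mb and 0.143 at 60 and 80 Mb by exact permutation, so none passed. Against E1-KO and E3-KO alone, without the low values of E2-KO, the differences were 0.25, 0.48 and 0.65 (exact permutation p = 0.0667 at each distance, the smallest that 15 choices allow).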

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

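The measures of decay with distance and every test named here were chosen after the values were seen. Genotypes on opposite sides of WT were not tested against each other. In reads per interaction both E1-KO libraries lay above and both E1&E3-dKO libraries below the WT libraries, a log2 difference of 1.66 between those genotypes. In contacts at 40 Mb against 1 Mb, E1-KO, E3-KO and E1&E3-dKO lay above and E2-KO below both WT libraries, with untested log2 differences from E2-KO of 0.33, 0.24 and 0.53. The same held at 60 Mb, with 0.32, 0.33 and 0.81, and at 80 Mb, with 0.46, 0.45 and 1.11. E1&E3-dKO exceeded the single knockouts, E2-KO included, by 0.59 at 60 Mb and 0.80 at 80 Mb (exact permutation p = 0.0357 for both, adjusted 0.143), and E1-KO and E3-KO alone by 0.48 and 0.65 (exact permutation p = 0.0667, the smallest possible).

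The genotype difference in contacts at 40 Mb against 1 Mb was weighed against technical sources. Recovered depth is argued against, since after removal of a linear trend in its log2 the genotype test still gave p = 0.00317 (exact permutation). So is the series of titles, with p = 0.00185 over pairings of equal title make-up (exact permutation). A floor of random ligation adds the same amount at every distance. In E1&E3-dKO replicate 2 the excess at 10 and 20 Mb fell short of the floor needed by 1.30 percent of the 1 Mb level. The WT libraries differed there by 0.515, but the E3-KO libraries by more, with 6.58% and 7.61% at 10 Mb and 5.31% and 6.14% at 20 Mb. At 40, 60 and 80 Mb E1&E3-dKO replicate 2 stood at 4.11%, 2.71% and 2.13%, against 3.00%, 1.52% and 0.990% in WT. That is a similar excess at each distance, as a floor gives, so the test cannot decide for this library. In E1&E3-dKO replicate 1 the shortfall was 0.574, which leaves a floor possible. An effect of the deletions may remain, untested, and so may a difference between clones or in the exonuclease combination, which the labels do not give per library.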

How the results depend on the processing

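Tests on interactions under 2 Mb, on the adjusted p of WT replicate 2 and on the decay were chosen after the data were seen. Of 1084 alternative values 890 stayed within the spread between replicates, within 1.5 times a count, or on their side of a test's threshold, 180 moved further, 4 came to pass the threshold, 0 ceased to and 10 tested values reversed. The 890 include 19 differences from WT, smaller than that spread, that changed sign, among them the number of interactions in E1-KO (from -0.05 to as much as 0.71) and in E3-KO (from 0.52 to -0.21), and reads in E3-KO (from -0.21 to as much as 0.29); 222 of 272 values at named regions were kept and 0 reversed. Except where a limit shows it, the cause was not tested. Genes could not be placed on mm9, so interactions and TADs at gene loci were not run. The lists rest on few reads: interactions with at most 3 reads made up 6.38% of the list in E1-KO replicate 1 and 83.8% in E1&E3-dKO replicate 2. Replicate numbers did not pair the libraries (r of boundary differences from -0.0816 to 0.0329, and of interaction differences from -0.0708 to 0.207, with 2 of 10 over 0.1); with the replicate block, exact permutation p of the decay was 0.00833.

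At an adjusted p of 0.001 the spread of distance within genotypes was 0.402 (exact permutation p = 0.0381; 0.0381 to 0.851 over alternatives), E1-KO lost 5 interactions and E1&E3-dKO lost 6 and gained 7. With the same number of best interactions the E2-KO distance differed by -1.27 and its reads by 1.24, the overlap difference was 0.0407 (exact permutation p = 0.0275; 0.0275 to 0.214 over alternatives), E2-KO gained 113, E1&E3-dKO 9 and all 3 genotypes 2. With identical bins E2-KO lost 16, E3-KO lost 7 and gained 38, E1&E3-dKO lost 18, and all 3 lost 3 and gained 4; within 2 bins E3-KO lost 1. The overlap coefficient gave 0.0617 (exact permutation p = 0.0286). With the adjusted p of WT replicate 2 doubled E1-KO lost 6. Under 2 Mb the number in E1-KO differed by 1.70, its distance by -0.24 and its reads by 0.19, E2-KO reads by -0.39, knockout reads reversed to -0.19, and losses were 2 in E1-KO, 2 in E2-KO, 0 in E3-KO and 3 in E1&E3-dKO.

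With TADs in the upper 75% of scores E2-KO gained 876 boundaries and all 3 gained 2 TADs. With the same number of best TADs E2-KO lost 821 boundaries and gained 396, E3-KO gained 268, E1&E3-dKO 355 and all 3 gained 8; gained TADs were 97, 130, 125 and 1. Within 10 kb all 3 lost 92 boundaries; within 50 kb losses were 246 in E2-KO, 225 in E3-KO, 283 in E1&E3-dKO and 33 in all 3. At a reciprocal overlap of 50% E2-KO gained 510 TADs and all 3 lost 25, and at 90% all 3 lost 75. The decay at 40 Mb against 2 Mb differed from WT by 0.0676 in E1-KO; against 100 kb by 0.43 in E1-KO, 0.18 in E3-KO and 0.58 in E1&E3-dKO; at 60 Mb by 0.21 in E3-KO and 0.69 in E1&E3-dKO; at 80 Mb by 0.28, 0.27 and 0.93 in E1-KO, E3-KO and E1&E3-dKO.

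Leaving out each library in turn asks for presence or absence in the remaining one only, which loosens the rule for the genotypes compared; leaving out a library of another genotype moved some counts slightly down, as when lost interactions in E1-KO went from 10 to 8 without E2-KO replicate 1. Lost interactions ranged from 8 to 984 in E1-KO, 5 to 1036 in E2-KO, 2 to 1036 in E3-KO, 10 to 1071 in E1&E3-dKO and 0 to 943 in all 3; gained from 33 to 711, 274 to 3040, 24 to 1239, 16 to 5833 and 1 to 12. In the same order lost boundaries ranged from 439 to 2301, 495 to 1804, 328 to 1860, 417 to 1949 and 57 to 777, gained from 363 to 2630, 1352 to 11165, 507 to 4718, 626 to 5103 and 15 to 102. Lost TADs ranged from 255 to 1551, 436 to 1752, 208 to 1384, 298 to 1560 and 45 to 838, gained from 201 to 1637, 236 to 7031, 227 to 3072, 205 to 3204 and 6 to 34. Differences from WT ranged in distance from -2.12 to -0.85 in E1-KO and -1.14 to 0.0489 in E2-KO, in reads from 0.58 to 1.91 in E1-KO, -0.42 to 1.00 in E2-KO and -0.0107 to 0.32 over knockouts, in number from 0.14 to 2.97 in E1&E3-dKO, -0.78 to 0.67 in E1-KO, 0.45 to 2.18 in E2-KO, -0.21 to 1.24 in E3-KO and 0.11 to 1.56 over knockouts, in TADs from 0.40 to 1.32 in E2-KO and in decay from 0.28 to 0.45 in E1&E3-dKO. Overlap differences ranged from -0.0114 to 0.0442 for boundaries, -0.0154 to 0.0589 for TADs (exact permutation p = 0.0328 without E2-KO replicate 2; 0.0328 to 0.684 over left-out libraries) and -0.0088 to 0.0214 for interactions. Boundary and TAD overlap reversed without WT replicate 1 (-0.00686, -0.00797), WT replicate 2 or E1-KO replicate 2 (-0.00567, -0.0123), TAD overlap also without E1-KO replicate 1 (-0.00177), and interaction overlap without E2-KO replicate 1.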

Other observations

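All of the tests here were chosen after the result was seen, and 3 were redefined after a first value. TADs on chromosome X were shorter than on autosomes in 9 of 10 libraries and of equal length in E2-KO replicate 1. The median length was 150 kb against 250 kb in WT replicate 1 and 165 kb against 270 kb in E1-KO replicate 1. The mean ratio over libraries was 0.613 ± 0.160 (SD, n = 10; exact sign test over 9 libraries, p = 0.00391). The slope of autosomal TAD length on depth gives a ratio of 0.749 where depth is divided by 2, as for a chromosome present in 1 copy. The 9 libraries with shorter TADs lay below this, from 0.45 in E1-KO replicate 2 to 0.692 in E1&E3-dKO replicate 2. That slope was fitted between libraries and its uncertainty was not carried over. Coverage of X may thus account for part of the shortening, and the remainder was not tested.

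The higher number and shorter length of TADs in E2-KO may follow from its lower recovered depth. Reads at recurrent interactions did not rise with that measure (log-log slope -0.0870), so it may not stand for the reads of a library. Outside E2-KO the number fell with depth, with Spearman's rho of -0.964 over 7 libraries, and the E2-KO libraries lay on average -1.43 residual SD from the line of those libraries, which argues against an excess of TADs from the E2 deletion beyond depth. The value first examined, for E2-KO replicate 2 alone, was -0.324, and replicate 1 lies below the depth range of the line. WT replicate 2 lay 2.80 residual SD above the line of the 9 other libraries and -1.16 SD from it with its depth divided by 2, as a doubled count of contacts in that library would give. After removal of the depth line the genotypes did not separate over 9 libraries (exact permutation p = 0.650).

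Interactions held by at least 5 libraries might come from contacts, or from copied or reordered sequence relative to the reference genome. Contacts would rise with depth with a slope near 1. Reads had a log-log slope of -0.0870 on recovered depth (jackknife SE 0.0750, 207 interactions). In the form first examined, at the 26 interactions of all 10 libraries, it was -0.178. There E2-KO replicate 1 had a median of 23.5 reads at a depth of 0.0147 and WT replicate 1 of 12 at 0.191. Reads from copied or reordered sequence would also rise with the reads of a library, so the slope cannot separate these sources. Whether recovered depth tracks the reads of a library could not be tested, since those are unknown. Reordered sequence would put called neighbours on a diagonal, and members with a diagonal neighbour outnumbered those with a one-ended neighbour by a ratio of 1.04 (bootstrap interval 0.92 to 1.18), which leaves it open. Of the interactions gained in E2-KO, 45.8% joined windows that were recurrent in the other 8 libraries, and 56.4% in the form first examined, whose windows included E2-KO itself. The share of 1.91% among interactions of 1 library is no baseline, since those were selected for not recurring, and the shares of the other genotypes are not compared because their libraries define the windows. A shared source of both stays open. The biological side was not tested.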
